A study of Mus musculus with 6 samples.

How the data were processed

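RNA of 3 ES cell samples and 3 TS cell samples was hybridised to 2-colour Agilent oligonucleotide arrays. Per the labels, each sample carried Cy3 and a universal mouse reference RNA carried Cy5 on every array, with no dye swap. Samples were grouped by their titles. The extraction protocol given with the ES samples describes TS cells, so the group rests on title, source and growth protocol. The deposited intensity values of each array were made with Agilent Feature Extraction version A.6.1.1, per the file headers: mean spot intensity and median local background in each channel, and processed signals, with background correction on and LOWESS parameters for the dye normalisation. Per the file headers, the log10 ratio of the 2 processed signals is Cy5 over Cy3. The authors also deposited a value table on a log10 scale, with a median of 2.90 on all 6 arrays. It follows the log10 processed Cy3 signal of the same array at correlations of 0.984 to 0.994, and its array-to-array differences follow the ratio; its exact scaling and centring stay unknown.

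Each array held 22575 spots, of which 322 were positive and 314 negative controls. The same layout was found on all 6. Background was corrected with normexp at an offset of 50, and ratios were normalised by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Ratios were turned to sample over reference, so that the common reference cancels in ES minus TS. A total of 925 spots marked in either channel as non-uniform or as population outliers were left out; saturated spots were kept. A probe was kept if its Cy3 signal was well above background and free of Cy3 marks on at least 2 arrays of a group. This removed 342 of 21939 probes, and 42 more had no value left in one group, so 21555 were tested. With lmFit and eBayes the groups were compared in a two-sided moderated test with Benjamini-Hochberg adjustment, and probes were called at an adjusted p of 0.05 with at least a 2-fold difference. An offset of 50 shrinks the folds of dim probes. In 4 called probes one group was above background on no array, so that their folds are bounds; none of the named genes was among them, and no called probe was saturated on all arrays of a group.

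Probes are named in the files by cDNA clone (21542) or by a sequence record (397). RefSeq accessions were matched without versions to a gene table of assembly GRCm38.p6: 113 of 117 matched. A GenBank locus name was given a symbol only where its abbreviation belonged to a single gene of that table, which named 29 more, for 142 probes with a symbol. No build is named in the files, so no coordinates are given. No gene name was guessed for a clone.

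Gene lists and the rule for named genes were fixed before the data were examined. The rule took up to 12 called genes with the largest fold in each direction whose groups do not overlap, up to 4 members of each list (called ones by fold, then the brightest), and a set of known ES and TS markers. It gave 22 genes, of which 2 are not reported here. Of those markers, Pou5f1, Nanog, Sox2, Zfp42, Eomes, Elf5, Tfap2c, Gata3, Hand1, Ascl2, Xist, Actb and Gapdh have no named probe here. A list member counts as measured only where a tested probe has a symbol, so probes without a symbol may still measure further members. The lists for fibroblasts, imprinted genes, cell cycle, glycolysis, germ cells, sex-linked genes and housekeeping genes had no such member. Feeder carry-over was therefore not assessed. Each gene was represented by its brightest probe. Lists with at least 3 measured members were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over 3 lists. The moderated test and the calling rule were tried on simulated log ratios for 20988 probes in 3 arrays against 3. All 50 probes changed by 1.5 on the log2 scale were called, as were all 50 changed by 2 and all 50 changed by 3. Of 50 changed by 0.5, which lies below the 2-fold limit, 46 passed the adjusted p and none was called. Of 20788 unchanged probes 0 were called and 8 passed the adjusted p alone. Independent noise was added to ratios already normalised, so background correction, normalisation and the filter were not tested. Far fewer probes were changed than passed the adjusted p in the real comparison.

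The alternatives were no background correction, an offset of 10, the software's processed signals, median centring, loess followed by Aquantile, Cy3 alone with quantile normalisation, no filter, both channels above background on every array, the deposited value table, eBayes with trend and robust options (statmod 1.5.0), the replicate number as a block, leaving out each array in turn and, chosen after seeing the data, keeping the marked spots. A fit with the marked spots kept had been seen before they were left out.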

Results

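Gene expression was measured in mouse embryonic stem (ES) cells and trophoblast stem (TS) cells with 60-base oligonucleotide arrays read in 2 colours. ES cells are grown from the inner cell mass of the blastocyst, and TS cells from its outer layer, the trophectoderm, or from the extraembryonic ectoderm that arises from it. The ES cells were the R1 line, from a hybrid of 129X1/SvJ and 129S1/Sv mice, kept on gelatin with the cytokine LIF. The TS cells came from ICR embryos at embryonic day 3.5 and embryonic day 6.5 and were kept with FGF4 and medium conditioned by feeder cells. There were 3 arrays of each group. On each array the sample carried Cy3, and a pool of RNA from 11 mouse cell lines, the same on all 6 arrays, carried Cy5. Strain, culture medium and cell type differ together between the groups, so their contributions cannot be told apart. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

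The scanner software marked nearly all probes as well above background. Between 92.5% and 99.9% of the 21939 probes were so marked in the Cy3 channel, and between 92.1% and 98.5% in the Cy5 channel. The highest share in each channel was that of TS replicate 3, which also had the highest median background-subtracted signal at negative controls. That median was 7.89 in Cy3 and 30.8 in Cy5. The median background-subtracted Cy3 intensity ran from 76.0 to 86.8 in the ES arrays and from 95.3 to 139.3 in the TS arrays. The number of arrays limits the precision. Log2 ratios correlated across probes at 0.98 to 0.984 between ES arrays, at 0.959 to 0.986 between TS arrays and at 0.703 to 0.723 between an ES and a TS array; probes are not independent replicates. The first principal component held 89.0% of the variance and parted the groups. TS replicate 3 lay farthest from its group, with an SD of 0.103 around the group mean against 0.060 to 0.069 for the other 5 arrays.

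The study compared ES with TS cells to find genes that may be predominantly expressed in the inner cell mass. Krt18, a keratin of simple epithelia, was 13.9-fold higher in TS cells (standard error 0.06 on the log2 scale, 3 arrays of each group). Msx2, a homeobox gene, was 2.91-fold higher in TS cells, and Fgfr2, a receptor of fibroblast growth factors, 2.44-fold higher. Of 21555 probes tested, 873 differed by at least 2-fold at an adjusted p under 0.05 in limma's moderated test, 367 higher in ES cells and 506 higher in TS cells. These are referred to as called. At the adjusted p alone, 7719 probes differed, 3554 higher in ES and 4165 higher in TS cells. All 3 arrays of one group lay above all 3 of the other in 47.6% of the 20988 tested probes with 6 values, where chance gives 10%. Of the called probes, 61 were at least 4-fold higher in ES cells and 83 at least 4-fold higher in TS cells. The number called depended on the treatment of background: 278 probes were called without background correction and 1199 with a smaller offset. The scanner software's processed signals, which differ in both background correction and dye normalisation, gave 1454.

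**Figure D1:**
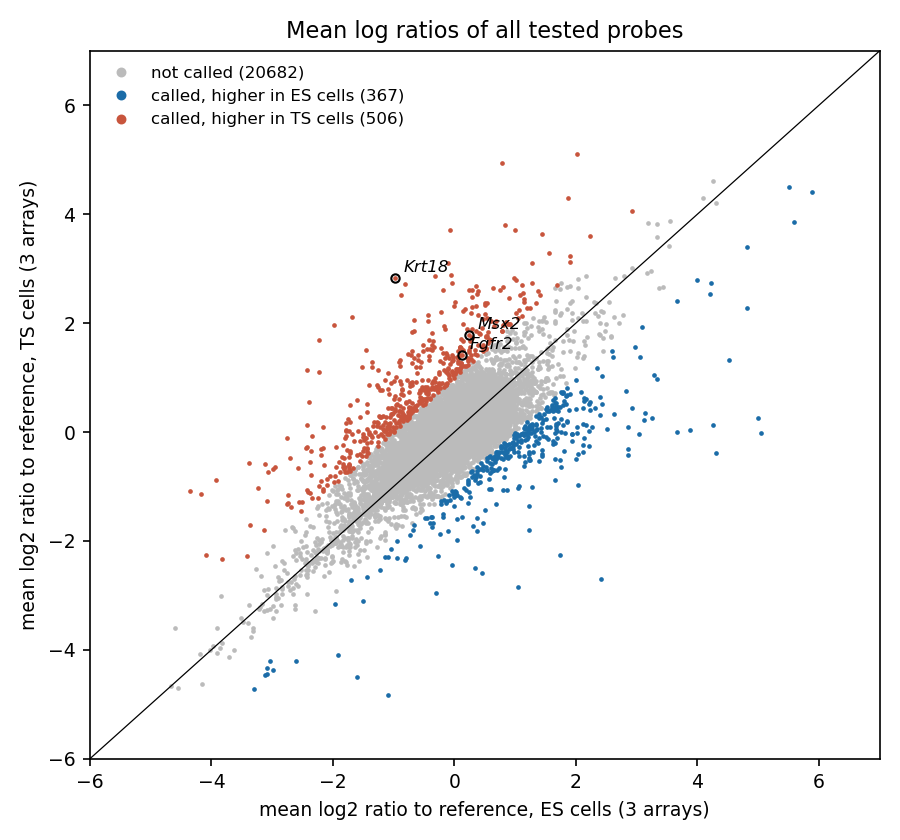
Mean log2 ratio of sample to reference RNA in the 3 TS arrays (vertical axis) against the mean in the 3 ES arrays (horizontal axis) for each of 21555 tested probes, with the line of equal ratios. The 367 probes called higher in ES cells lie below the line and the 506 called higher in TS cells above it, and circles mark Krt18, Msx2 and Fgfr2.

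Krt18 (NM_010664) had a log2 ratio to the reference of -0.98 ± 0.07 (SD, n = 3) in ES cells and 2.82 ± 0.07 (SD, n = 3) in TS cells. The difference, ES minus TS, was -3.79 with a standard error of 0.06 (limma adjusted p = 1.17e-08). All 3 TS arrays lay above all 3 ES arrays. Krt18 was called in 19 of 19 settings, with differences from -3.89 to -3.12, the smallest without background correction. The 19 settings include the main one and are not independent checks. Aquantile, no filter, the trend and robust options and the replicate block left its difference at -3.79.

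Of 5 measured members of the trophoblast stem cell list, 2 were called higher in TS cells, none higher in ES cells and 3 were not called; adjusted over the list alone the counts were the same. Msx2 (NM_013601) was higher in TS cells, with a difference of -1.54 and a standard error of 0.08 (limma adjusted p = 1.37e-06). Fgfr2 (NM_010207), through which FGF4 acts on TS cells, differed by -1.29 with a standard error of 0.13 (limma adjusted p = 7.42e-05). Its log2 ratio was 0.12 ± 0.06 (SD, n = 3) in ES and 1.41 ± 0.30 (SD, n = 3) in TS cells. Cdx2, a transcription factor needed for trophectoderm, was also higher in TS cells, but only 1.22-fold (difference -0.29, standard error 0.04, limma adjusted p = 0.000446). Esx1, a homeobox gene of the extraembryonic lineage named here after its values were seen, was 1.96-fold higher in TS cells (limma adjusted p = 3.32e-06) and was called in 4 of the alternatives, 1 of them without ES replicate 3. Ets2 had a difference of -0.02 that changed sign with the normalisation and did not pass (limma adjusted p = 0.851). The list's median difference was -0.97. Against all other probes its shift had an adjusted p of 0.00315 (camera, correlation preset at 0.01), and an adjusted p = 0.0978 with an estimated correlation, at which it no longer passed. On balance its genes moved towards TS cells (fry adjusted p = 0.000192). Without background correction neither Msx2 nor Fgfr2 reached 2-fold, at -0.50 and -0.38. With an offset of 10 they were at -1.95 and -1.7, and each was called in 18 of 19 settings.

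Markers of the ES cell side were nearly unmeasured by name. The single measured member of the pluripotency list, Fgf4, the growth factor that inner cell mass cells secrete, was 1.18-fold higher in ES cells (difference 0.24, standard error 0.06, limma adjusted p = 0.0138) and was not called. It passed the adjusted p in 16 of 19 settings, with an adjusted p of 0.882 with Cy3 alone and 0.0586 without ES replicate 1. Esrrb, a nuclear receptor used by both kinds of stem cell and the single measured member of the list of genes expressed in both, had a difference of 0.08 (limma adjusted p = 0.294), which was -0.00098 without background correction. Neither was called when adjusted over the list alone. Of the LIF and STAT3 list, Gbx2 was 1.21-fold higher in ES cells (difference 0.28, limma adjusted p = 0.00434), and Il6st, the shared receptor chain of the LIF family, had a difference of 0.12 (limma adjusted p = 0.223). Gbx2 passed the adjusted p in 18 of 19 settings, and Il6st in 3 of 18, with a difference of 0.74 from the processed signals (limma adjusted p = 0.0299). None of the 2 measured members was called over all probes or adjusted over the list alone. The Esrrb and Il6st probes were dim, with a mean log2 intensity of 6.26 and 6.29. They were not above background in both channels on every array. Their small differences therefore do not show equal expression.

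Of the FGF and ERK signalling list, 5 members were measured. Fgfr2 was called higher in TS cells, and the other 4 were not called, with the same counts adjusted over the list alone. By the adjusted p without the fold limit, 1 member higher in ES and 1 higher in TS cells passed over all probes. Adjusted over the list alone, 1 higher in ES and 3 higher in TS cells passed. Fgfr4, also on the list, had no probe with a symbol. MMFGFR4M, a record whose abbreviation matched no single gene, was called 2.2-fold higher in TS cells (limma adjusted p = 1.85e-05). That record was picked after the values were seen and is not counted in the list. Fgfr3 had a difference of 0.12 (limma adjusted p = 0.145), which without TS replicate 1 was 0.18 and passed (limma adjusted p = 0.0384). Etv4 had one of -0.18 (limma adjusted p = 0.0946), which without TS replicate 3 was -0.26 and passed (limma adjusted p = 0.00254). The list did not stand apart from other probes (camera adjusted p = 0.788, and adjusted p = 0.856 with an estimated correlation). Tested against no change, its genes did not pass on balance (fry adjusted p = 0.0537) and passed for change in either direction (fry adjusted p = 0.00123). Of the list for Nodal, TGF-beta and BMP signalling, Fst, an antagonist of activins, was 1.27-fold higher in ES cells (limma adjusted p = 0.00994) and Bmpr1a, a BMP receptor, 1.25-fold higher in TS cells (limma adjusted p = 0.00660). They passed the adjusted p in 15 and 17 of 19 settings. Neither of these 2 measured members was called over all probes or adjusted over the list alone.

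Of the differentiated trophoblast list, none of 3 measured members was called, over all probes or adjusted over the list alone. Dlx3, a homeobox gene of the placental labyrinth, was 1.27-fold higher in TS cells (difference -0.35, standard error 0.08, limma adjusted p = 0.00622), and passed the adjusted p in 17 of 19 settings. Tpbpa, a spongiotrophoblast marker that was well above background on 2 of the ES arrays and all 3 TS arrays, differed by 0.08 (limma adjusted p = 0.310), and Cebpa by 0.06 (limma adjusted p = 0.310). The Tpbpa probe was dim (mean log2 intensity 6.14) and not above background in both channels on every array. Its small difference therefore does not show equal expression. The list's median difference was 0.06 and its mean -0.07, and it did not stand apart from other probes (camera adjusted p = 0.951, and adjusted p = 0.954 with an estimated correlation). Tested against no change, its genes did not pass on balance (fry adjusted p = 0.363) or in either direction (fry adjusted p = 0.106).

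Further lists had 1 or 2 measured members. Krt18 was the single one of the epithelial list and was called, also when adjusted over the list alone. Thbd, of the endoderm list, differed by 0.01 (limma adjusted p = 0.932). Gsc and Evx1, of the list for early germ layers, differed by -0.02 and 0.03 (limma adjusted p = 0.752 and 0.659), and Cbx2, of the list for chromatin repression, by 0.01 (limma adjusted p = 0.864). None of these 4 was called over all probes or adjusted over the list alone, and the sign of each changed under some of the alternatives. The Gsc probe was dim (mean log2 intensity 6.15) and not above background in both channels on every array, so its small difference does not show equal expression.

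**Figure D2:**
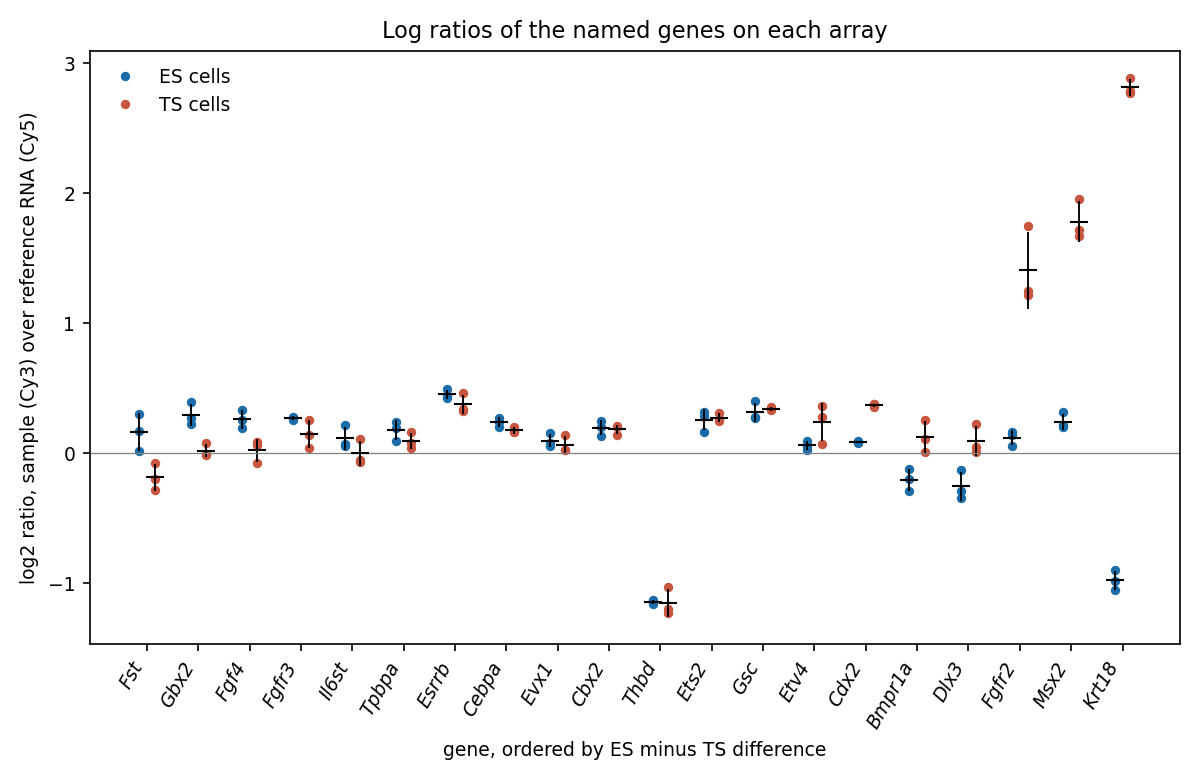
Log2 ratio of sample to reference RNA on each array for 20 named genes, in order of the ES minus TS difference, with the 3 ES and 3 TS arrays as points and the group mean ± SD as black marks. Fgfr2, Msx2 and Krt18 are parted on the TS side, while the groups of the other genes shown lie within 0.35 of each other.

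Most of the called probes carry no gene symbol. Of the 873, 857 are named by a cDNA clone and 16 by a sequence record, of which 5 have a symbol. The 11 others are known by their record's locus name, 6 of them 2.01-fold to 7.94-fold higher in ES cells and 5 of them 2.16-fold to 3.96-fold higher in TS cells. The next 2 were chosen after their values were seen. MMU25096 was 7.94-fold higher in ES cells (limma adjusted p = 2.14e-07). MUSREX1, whose abbreviation is listed under both Zfp42 and Rexo1 and was therefore not resolved, was 2.79-fold higher in ES cells (difference 1.48, standard error 0.09, limma adjusted p = 3.55e-06).

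Among clone-named probes measured on all 6 arrays, H3029H05-3, with the sequence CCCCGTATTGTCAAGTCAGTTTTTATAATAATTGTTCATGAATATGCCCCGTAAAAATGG, was 26.7-fold higher in ES cells (difference 4.74, standard error 0.09, limma adjusted p = 1.17e-08). H3155A06-3, with the sequence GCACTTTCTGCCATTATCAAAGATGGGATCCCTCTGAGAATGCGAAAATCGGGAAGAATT, was 17.4-fold higher in ES cells. G0101E03-3, with the sequence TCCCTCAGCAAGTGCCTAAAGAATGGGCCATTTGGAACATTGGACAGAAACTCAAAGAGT, was 17.8-fold higher in TS cells (difference -4.15, standard error 0.08, limma adjusted p = 1.49e-08). H3118H06-3, with the sequence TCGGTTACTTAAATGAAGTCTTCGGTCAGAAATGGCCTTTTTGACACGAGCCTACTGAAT, was 15.4-fold higher in TS cells. These 4 were the largest differences in each direction among such probes, and were picked by size. In 17 of the 873 called probes, 7 higher in ES and 10 higher in TS cells, only 1 array was left in a group once marked spots were removed. Their calls rest on the other group's spread and on that shared over all probes, and no fold is given for them.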

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

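Keeping the marked spots was chosen after seeing the data; the other alternatives were planned. None of the 873 called probes changed sign under any of them where it was tested. Without background correction 278 probes were called, 118 higher in ES and 160 higher in TS cells, and differences of the called probes shrank to 0.604 of their size. With the processed signals 1454 were called, 640 higher in ES and 814 in TS cells, and with the authors' deposited log10 values 1416 were called, 628 and 788 in the same order. At the adjusted p alone, by construction with no fold limit, 7719 passed. Loess with Aquantile leaves ratios as they are. Leaving out 1 array gave 863 to 877 calls, 359 to 378 higher in ES and 498 to 514 higher in TS cells; without TS replicate 3 there were 876. The share of calls higher in ES cells was 42.0%, and from 37.2% with median centring to 49.8% with Cy3 alone; this share was looked at as a sign of ratio bias and not pursued. The median correlation within groups fell to 0.916 with processed signals.

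Same-numbered arrays had residual correlations of 0.10, 0.034 and 0.027. ES replicates 1 and 3 and TS replicates 1 and 2 matched their own number best in the other group. ES replicate 2 and TS replicate 3 did not. Correlations this small, over so few arrays, cannot settle whether the numbers pair the samples. With the replicate block 875 probes were called, 368 higher in ES and 507 in TS cells. A block by scan date was not run, since the files used here give no scan date, and no gene in a list had more than 1 named probe, so a mean over probes was not run.

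Without background correction Msx2 (-0.50) and Fgfr2 (-0.38) fell below 2-fold, and the trophoblast stem cell and FGF lists had no called member. The trophoblast stem cell list had 3 with an offset of 10, processed signals, the deposited log10 values and without ES replicate 3, where Esx1 was called. Fgf4 (adjusted p 0.882), Gbx2 (0.523), Fst (0.173), Bmpr1a (0.261) and Dlx3 (0.209) did not pass with Cy3 alone. Some genes that did not pass in the main setting passed the adjusted p elsewhere, uncalled: Il6st in 3 settings, Etv4 in 2, and Gsc, Cebpa, Tpbpa and Fgfr3 in 1 each. Uncalled genes changed sign. Without background correction these were Esrrb (-0.00098), Cebpa (-0.02), Evx1 (-0.015), Gsc (0.0065) and Cbx2 (-0.0052). With an offset of 10 they were Thbd (-0.07) and Gsc (0.15). Processed signals gave Thbd -0.26, Evx1 -0.17 and Gsc 0.83 (limma adjusted p = 0.0427), and the deposited log10 values Thbd -0.26 and Evx1 -0.17. Median centring gave Ets2 0.0107, Thbd -0.0103 and Gsc 0.13, and Cy3 alone Ets2 0.0369, Cebpa -0.17 and Evx1 -0.0286. With 1 array left out, Cbx2 ran from -0.0137 to 0.0447, Ets2 from -0.0468 to 0.0294, Gsc from -0.0661 to 0.000269 and Thbd from -0.031 to 0.071. The differentiated trophoblast list turned at camera p 0.801 (offset 10), 0.981 (processed signals) and 0.547 (median centring). The cause was not tested.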

Other observations

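The tests on clone prefixes, on the splits of the arrays and on the share of ES RNA as the main part of a distance were chosen only after the result was seen, and the other tests on TS replicate 3 after it was seen to lie apart. Further genes with a symbol, named after their values were seen, passed the adjusted p below 2-fold, and each kept its direction under all alternatives that gave a value. Cbx3, a heterochromatin protein, was 1.97-fold higher in ES cells (limma adjusted p = 1.71e-06). Epha2, an ephrin receptor, was 1.45-fold and Notch1 1.34-fold higher in ES cells. Itgav, an integrin chain, was 1.55-fold higher in TS cells, Adam15 1.47-fold, Ctnnb1, which encodes beta-catenin, 1.32-fold, and Akt1 1.31-fold. The 2-fold limit was passed by Cbx3 in 5 alternatives (up to 1.16 on the log2 scale) and by Itgav in 3 (up to -1.62). The apoptosis genes Bax and Bcl2 moved apart, Bax 1.23-fold higher in ES and Bcl2 1.14-fold higher in TS cells, but Bax passed in 10 and Bcl2 in 12 of 19 settings. Cebpb had no value because the reference channel was marked as non-uniform or an outlier on all 3 ES arrays and 1 TS array; with those spots kept it was 6.12-fold higher in TS cells (difference -2.61, limma adjusted p = 1.27e-08). Pairs of probes with identical sequence, 29 in all, differed by a median of 0.04 in their log2 difference.

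Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split called 873 probes, as many as in 1 of the 10, and the highest other split called 0.

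Called probes were unevenly spread over the first 3 characters of the clone names: 11 of 70 Fisher's exact tests passed. Probes higher in TS cells were in excess in C01, 58 of 979 (5.92% against 2.17% of the other clones, Fisher adjusted p = 9.60e-09). They were also in excess in C06, 33 of 422 (Fisher adjusted p = 6.32e-08). Probes higher in ES cells were in excess in G01 with 18 of 332 (Fisher adjusted p = 0.000401) and C03 with 23 of 557 (Fisher adjusted p = 0.00160). The same held for J09 with 9 of 142 (Fisher adjusted p = 0.00742) and C04 with 10 of 230 (Fisher adjusted p = 0.0396). The other tests that passed were shortages. Probes higher in TS cells were few in C03 (2 of 557), K05 and L08, and those higher in ES cells in K05 (0 of 507) and L09. Brightness was not tested for the shortages. Brightness is argued against for C01, C06 and C03, whose observed numbers were at least 1.28 times the highest of 1000 draws matched on intensity, and for J09 (1.12 times), but stays open for C04 (0.833) and for G01 (0.90), the brightest of these 6. A first bound of 1.5 times the highest draw was met by C06 (1.65) but not by C01 (1.29) and C03 (1.28), and was lowered to the highest draw after these values were seen. For C01, C06 and C03 the place on the array is argued against, since neighbouring probes of other prefixes differed by a mean of -0.06 (standard error 0.025) in the direction of the called probes. A candidate explanation is that clones of a prefix share a source library, which was not tested.

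TS replicate 3 lay 0.153 (SD of the log2 distance) from the mean of the other 2 TS arrays, against 0.102 for each of those. A stretched array is argued against, as a straight line took away 0.10% of the SD. A loess curve on intensity took away 0.124%. Each array had already been normalised by loess on intensity, so that curve could not decide whether a trend with intensity played a part. Called probes higher in ES cells lay at a median of 0.0338 and those higher in TS cells at -0.0135, the signs that some ES RNA in that sample would give, though medians of the other arrays reached -0.0285 and 0.0224. The difference ES minus TS took away 1.5% of the SD, which argues against such RNA as the main part. TS replicate 3 also had the highest median background-subtracted signal at negative controls in both channels, 7.89 in Cy3 and 30.8 in Cy5. The other arrays reached 6.46 (ES replicate 1) and 21.41 (TS replicate 2). Whether this bears on the distance was not tested. A separate culture stays among the open explanations, as untested.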
